A study of Schizosaccharomyces pombe with 31 samples.

How the data were processed

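RNA from the fission yeast Schizosaccharomyces pombe was sequenced on the Illumina platform. The labels list 31 samples: 6 of rapidly proliferating cells, 4 from each of 5 stages of a meiotic time course, 3 of cells under oxidative stress and 2 of a prp2 splicing mutant. Per the labels, proliferating cells were haploid, of h- mating type, grown in rich medium at 32 °C to an optical density of 0.2. The meiotic cells were diploids homozygous for h+ and for a temperature-sensitive pat1 allele, which enter meiosis when shifted to a higher temperature. Their starting point was at 25 °C in medium lacking nitrogen, and the later pools, spanning hours 1 to 8 in pairs, were at 34 °C in medium low in nitrogen, at an optical density of 0.5. Poly(A) RNA was selected and copied into cDNA with an oligo(dT) primer, per the labels' protocols, and part of the proliferating RNA was instead depleted of uncapped RNA and primed with random hexamers. The pooled meiotic RNA was amplified by in vitro transcription and the proliferating RNA was not, per the labels' protocols.

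The values analysed were coverage signal tracks, deposited as 54 whole-series files covering 6 libraries, named wt and M0 to M4, with 3 tracks per library and 3 chromosomes per track. They belong to the series and not to single samples, and the oxidative stress and prp2 samples were not analysed here. A library here means 1 such named set of tracks, which may pool several of the listed samples. Reading wt as the proliferating cells and M0 to M4 as the 5 meiotic stages in time order rests on these names alone. No label states it, so the libraries are called by their own names throughout, and any statement on culture or amplification of a library depends on that reading. The deposited names of the wt tracks hold the word filtered and those of M0 to M4 do not. What was filtered is not known here. The deposited signal had no header. The values themselves showed it to be 1 plus the natural log of the read coverage at a base, divided by the total coverage of the track, and 0 at uncovered bases. Undoing this gave whole-number coverage at every base, the largest distance from a whole number being 2.28e-08. The aligner, its settings and the genome build are not given in the sources used here.

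Within each library no base was lower in the track ending in 2 than in that ending in 1, nor lower in the track ending in 3 than in that ending in 2. The 3 tracks were therefore nested sets of reads and not replicates. The track ending in 3, which holds the most coverage, was used for all values, the other 2 as alternatives. No library had a replicate, so every difference describes these libraries and has no p-value. The rule written for this case before the data were examined was applied in place of a test between replicates.

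Gene models came from the assembly ASM294v3. The tracks ran 1867, 1800 and 900 positions past the ends of its chromosomes I, II and III, with no coverage there. The level of a gene was the log2 of its mean coverage over all annotated exonic bases, centred on the median of the 5113 protein-coding genes in the same track. The annotation holds 12606 genes in all. Genes with 3 read equivalents or fewer were set to the level that 3 would give, and a difference against such a gene is a bound. Read equivalents are the summed coverage divided by the most common length of isolated covered stretches, which was 40 bases in wt, 36 in M0 to M3 and 29 in M4. A gene was called higher or lower when its log2 difference was at least 1, its direction was the same in all 3 tracks, and the higher of its levels was at or above the 25th percentile of protein-coding levels over the 6 libraries (a log2 level of -0.94). M1, M2, M3 and M4 were each compared with M0, and M0 with wt. The 4 comparisons with M0 share that library, so overlaps between them were not read. Errors given as ± are counting standard errors from read equivalents. They do not cover variation between cultures, and reads duplicated by amplification are not independent molecules, so they are too small.

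Before the data were examined, 24 gene lists were fixed: recombination and cohesion, horsetail movement, meiotic divisions, spore membrane and wall, late sporulation regulators, mating and pheromone, P-cell-specific, M-cell-specific, nitrogen starvation, cytosolic ribosomal proteins, ribosome biogenesis, DNA replication, mitotic M phase, histones, heat shock and chaperones, environmental stress, glycolysis, nuclear-encoded oxidative phosphorylation, proteasome, spliceosome genes named prp, meiotic RNAs removed through the protein Mmi1, genes named mug or meu, the wtf family, and genes with introns known to be regulated in meiosis. For 23 of them the median difference was placed among 10000 random protein-coding lists of the same size, matched on mean level in 20 bins, and called when outside the central 95%. In M0 against wt the Mmi1 list was not placed, because 2 of its 7 protein-coding members were above the floor. The list of genes with introns regulated in meiosis served for introns alone. Counts and medians used protein-coding members alone, so they leave out sme2, the noncoding member of the Mmi1 list. Several lists share members: the P-cell and M-cell lists overlap the mating list, and the Mmi1 and mug or meu lists overlap those of meiosis. Genes named in the text were, per comparison, the 10 called protein-coding genes with the largest rise and the 10 with the largest fall among those with a standard symbol and at least 300 exonic bases, up to 4 members per list with the largest absolute difference, the listed introns and the 10 with the largest called change, and the 5 noncoding genes with the largest called rise plus sme2. The text gives a selection of them. Values of single members of multigene families, which include duplicated ribosomal protein and histone genes, are uncertain, also where the text does not repeat it. So are values of genes that share bases with another gene, since the tracks do not mark strand.

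Introns of at least 40 bases that overlap no annotated exon were compared with their 2 flanking exons, and a change was called at a log2 difference of at least 1 with the same direction in all 3 tracks and the exons above the level floor in both libraries. Noncoding genes were used when clear of protein-coding exons, which left 1901. Alternatives planned before the data were examined were the other 2 tracks, the mean of log values in place of the log of the mean, the last 300 exonic bases, no centring, quantile normalization, no floor, a floor at the 50th percentile, a size rule of 1.5, the main track alone, 10 bases left out at intron ends, all exons of the gene, and a higher threshold for a covered base. After the data were seen, 3 more were added: leaving out bases within 40 bases of a 20-base window with at least 16 A or 16 T, using exonic bases of 1 protein-coding gene alone, and leaving out introns near such windows.

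Total coverage, in units of 1e6 bases, was 809 in wt, 648 in M0, 645 in M1, 591 in M2, 480 in M3 and 304 in M4. The median protein-coding gene held 1319 read equivalents in wt, 523 in M0, 599 in M1, 514 in M2, 331 in M3 and 174 in M4. The median counting standard error of a log2 difference over genes above the floor was 0.08 in M1 and in M2, 0.10 in M3, 0.12 in M4 and 0.07 in M0 against wt. The procedure was tested on simulated data in which 200 of the 5113 genes were changed, all at or above the median coverage of the library compared against. Recovery among less covered genes was therefore not tested. No unchanged gene was called in any comparison (0 of 4913), and 3-fold and 4-fold changes were recovered in full except 3-fold falls in M0 against wt, at 97.0%. Exact 2-fold rises were recovered at 52.9% in M4, the lowest value, to 82.4% in M1 and M2, the highest, and falls at 26.5% in M2 to 38.2% in M4, so genes near the size rule are often missed. For introns, 549 with read numbers well above the floor of 3 in both intron and exons were simulated from M0. There 195 of 200 4-fold changes were recovered, and 20 of 349 unchanged introns (5.73%) passed the size rule. The rate for introns with fewer reads, or at the depth of M4, was not measured. The simulation drew counting noise alone. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.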

Results

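The transcriptome of fission yeast was followed through meiosis and set beside that of growing cells, with read coverage at every base of the genome as the measurement. Coverage was analysed for 6 libraries, wt and M0 to M4, each present as 1 set of nested tracks that may pool several samples. Their names fit proliferating cells and 5 successive meiotic pools, but no label ties a name to a pool. In units of 1e6 read equivalents, the libraries held 20.2 in wt, 17.99 in M0, 17.93 in M1, 16.4 in M2, 13.3 in M3 and 10.5 in M4. With 1 library each, no difference below has a replicate check, and ± gives counting standard errors on the log2 scale. Levels are relative to the median protein-coding gene of the same library. That median, per base of total coverage, lay 1.17 higher in wt than in M0 on the log2 scale, 0.19 higher in M1 and 0.07 higher in M2, and differed by -0.20 in M3 and -0.79 in M4. These shifts are those of the largest track, and in the tracks ending in 1 and 2 they were 0.19 and 0.16 in wt, -0.54 and -0.49 in M3 and -0.65 and -0.62 in M4. In the largest track 72.7% of the M0 coverage and 14.5% of the wt coverage lay near A or T runs. If the names hold, M0 was grown at 25 °C and M1 to M4 at 34 °C in another medium, so stage, temperature and medium go together in every comparison of M1 to M4 with M0.

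**Figure D1:**
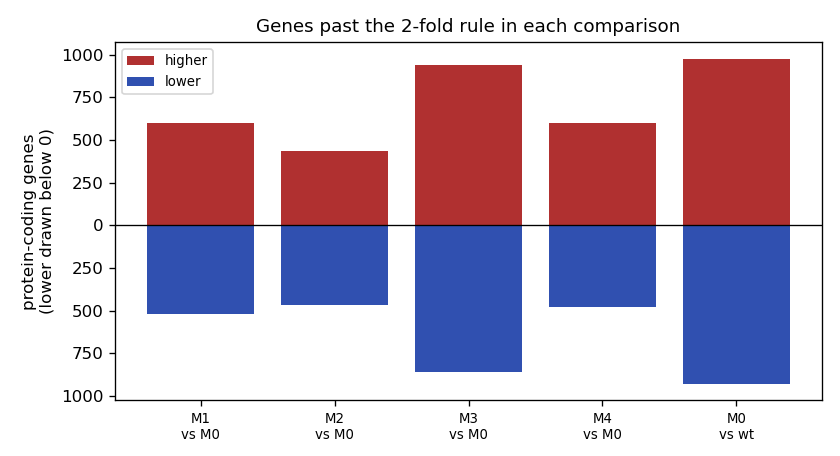
Number of protein-coding genes called higher (drawn upward) or lower (drawn downward) in each comparison, on a linear axis. Each bar comes from 1 library against 1 library, a library being 1 set of deposited tracks that may pool several samples. M3 had 937 higher and 858 lower genes against M0, and M0 had 976 higher and 930 lower against wt.

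M1 against M0 asked how transcript levels differed between the first library of the M series and the next. Genes for ribosomal proteins, chaperones, histones and meiotic recombination were higher in M1, and genes for nitrogen starvation, mating and stress defence were lower. Of 129 cytosolic ribosomal protein genes, none fell and all but 6 rose. The meiosis-specific genes hop1, whose product is part of the meiotic chromosome axis, and meu13, needed for pairing of homologous chromosomes, rose by 3.66 ± 0.08 and 3.79 ± 0.14. The amino-acid permease gene nrg1 fell by 5.91 ± 0.18. Of 4213 protein-coding genes above the floor, 602 rose and 519 fell.

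The largest rise in M1 was that of wis2 (SPAC1B3.03C, chromosome I, 4929854 to 4931163 on the minus strand), which encodes a cyclophilin co-chaperone, at 4.00 ± 0.07. Its mean coverage was 257 in M1 and 14.2 in M0. The gene mbf1, for a transcriptional coactivator, rose by 3.31 ± 0.08, mug10 by 3.19 ± 0.11, and the co-chaperone genes sti1 and wos2 by 3.02 ± 0.06 and 2.98 ± 0.04. The ribosomal protein genes rps1402 and rpp203 rose by 3.19 and 3.15, with the reservation that such genes have near-identical copies and that rpp203 shares all its bases with another gene. The largest falls included the alpha-glucosidase gene agl1, at -5.57 ± 0.16, the proline transporter gene put4, at -5.47 ± 0.22, the amino acid transporter gene isp5, at -5.02 ± 0.15, and mfm1, which encodes a precursor of the M-factor mating pheromone, at -4.51 ± 0.10. The alpha-galactosidase gene mel1 fell by 3.58 ± 0.27 and the uridine ribohydrolase gene urh1 by 4.44 ± 0.26.

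Among the meiotic lists, 11 of 18 recombination and cohesion genes above the floor rose in M1 and none fell. Their median difference was 1.51, at percentile 100 of the random lists. The meiotic cohesin gene rec8 rose by 2.13 ± 0.10 and the axis gene rec10 by 1.99 ± 0.10. Of 7 genes for the horsetail movement of the meiotic nucleus, 4 rose (median 1.62, percentile 100), among them bqt1, at 2.21 ± 0.13, which gathers telomeres, and the dynactin gene ssm4, at 2.12 ± 0.13. All 5 protein-coding members of the Mmi1 list above the floor rose (median 2.12, percentile 99.99), with the cyclin gene crs1 at 2.37 ± 0.15 and spo5 at 1.78 ± 0.05. The noncoding member sme2 was not called. The meiotic divisions list had 2 rises, 3 falls and 4 genes not called, with a median of -0.73 at percentile 1.69, a call lost with the track ending in 1 and with the higher floor. Its members mes1, a regulator of the second division, and cdc25, the mitotic phosphatase, fell by 1.64 ± 0.09 and 1.28 ± 0.10. Of 17 spore membrane and wall genes, 3 fell, none rose and 14 were not called (median -0.72, percentile 0.37), and the falls were the glucan synthase homologue mok14, the chitin deacetylase gene cda1 and the glucanase gene agn2, at -1.31, -1.23 and -1.12. None of 3 late sporulation regulators was called (median -0.56, percentile 22.1). Of 96 genes named mug or meu, 12 rose and 22 fell (median -0.46, percentile 0).

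Starvation and mating genes were lower in M1. Of 11 nitrogen starvation genes, 8 fell and none rose, with a median of -2.25 at percentile 0. The fall was 2.74 for the protease gene isp6 and 2.59 for the glutamate dehydrogenase gene gdh1. Of 22 mating genes 7 fell and none rose (median -0.78, percentile 0.02), among them map2, for the P-factor pheromone, by 2.57 ± 0.01. The P-cell-specific list had 2 falls among 5 genes (median -0.95, percentile 2.52, inside the central 95%), and the M-cell-specific list 3 among 6 (median -0.79, percentile 2.04, not called without bases near A or T runs or with no floor). Of 16 environmental stress genes, 7 fell and 1 rose (median -0.80, percentile 0.03). These falls included the glutathione S-transferase gene gst3, by 3.49 ± 0.11, the metallothionein gene zym1, by 2.64 ± 0.04, and the catalase gene ctt1, by 1.91 ± 0.06. Glycolysis had 6 falls among 15 genes (median -0.66, percentile 0.31), with tpi1 at -1.65. No gene of 35 for oxidative phosphorylation was called, at a list median of -0.56 and percentile 0.14. Of 16 wtf genes, from a family with many similar copies that includes spore killers, 5 fell (median -0.84, percentile 0.03).

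The ribosomal protein list in M1 had a median of 1.84 at percentile 100. Of 29 ribosome biogenesis genes, 13 rose and none fell (median 0.96, percentile 100), among them the snoRNP genes nop56 and nop58, at 1.64 ± 0.07 and 1.63 ± 0.04. Of 14 heat shock and chaperone genes, 11 rose and 1 fell (median 2.31, percentile 100), led by hsp90 at 3.27 ± 0.03 and the endoplasmic reticulum chaperone gene bip1 at 2.70 ± 0.04. In the libraries that share the growth temperature of M1, if the names hold, the list median was 2.11 in M2 and 2.26 in M3, both at percentile 100, and 0.50 in M4, inside the central 95% at percentile 97.4. Of 10 histone genes 8 rose (median 1.74, percentile 99.2), including htb1 at 2.06 ± 0.02 and the H2A.Z gene pht1 at 2.04 ± 0.05. DNA replication had 9 rises and 1 fall among 21 genes (median 0.74, percentile 99.96), with the Wee1-like kinase gene mik1 at 2.54 ± 0.08 and the ubiquitin ligase adaptor gene cdt2 at 2.03 ± 0.07. Mitotic M phase genes had 2 rises and 2 falls among 15 (median -0.31, percentile 11.4). None of 32 proteasome genes was called (median 0.12, percentile 81.7), and 1 of 17 prp genes rose, the helicase gene prp43, at 1.44 ± 0.12 (list median 0.45, percentile 95.4). Over genes above the floor, the differences of the 2 parts of a gene split at its middle had a correlation of 0.83 and a median gap of 0.32. With no centring 784 genes were higher in M1 and 387 lower.

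M2 against M0 gave the same question for the library named next. Chaperone, recombination and spore genes were higher in M2, and mating and nitrogen starvation genes were lower. The largest rise was that of spo5 (SPBC29A10.02, chromosome II, 2536150 to 2538254 on the plus strand), for an RNA-binding protein needed in the second meiotic division, at 4.93 ± 0.05, and the largest fall was that of map2 (SPCC1795.06, chromosome III, 986014 to 986684 on the minus strand), at -8.33 ± 0.06. Of 4263 genes above the floor, 437 rose and 466 fell.

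Other large rises in M2 were the small heat shock gene hsp16, at 4.92 ± 0.08, adg2, at 4.74 ± 0.05, mug15, at 3.74 ± 0.15, and the Hsp70 gene ssa1, at 3.55 ± 0.05. Large falls included put4 (-6.69 ± 0.37), nrg1 (-6.60 ± 0.24), isp7 (-5.75 ± 0.08), the claudin-like gene dni2 (-5.69 ± 0.15), the oligopeptide transporter gene isp4 (-5.50 ± 0.09), thi7, a transporter gene (-5.15 ± 0.17), and the kinase gene shk2 (-5.03 ± 0.10).

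Of 17 recombination and cohesion genes 12 rose and none fell (median 1.23, percentile 100), among them moa1, for the meiotic kinetochore regulator, at 3.05 ± 0.28, and hop1 and meu13 at 2.31 ± 0.09 and 2.34 ± 0.15. Of 6 horsetail genes 4 rose (median 1.33, percentile 99.99). The meiotic divisions list had 5 rises, 1 fall and 5 genes not called (median 0.79, percentile 99.75), and the rises included the forkhead transcription factor gene mei4, at 1.71 ± 0.11, and the meiotic cyclin genes crs1 and rem1, at 2.89 ± 0.15 and 1.27 ± 0.13. Of 19 spore membrane and wall genes, 9 rose and none fell (median 0.76, percentile 99.89), with the spindle pole body genes spo2 and spo13 at 2.44 ± 0.07 and 1.81 ± 0.08. Of 3 late sporulation regulators 1 rose, atf21, at 1.72 ± 0.07 (list median 0.83, percentile 93.4). All 7 protein-coding genes of the Mmi1 list rose (median 1.71, percentile 100), and its noncoding member sme2 was not called. Of 101 mug or meu genes 39 rose and 7 fell (median 0.64, percentile 100).

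Of 22 mating genes 13 fell and none rose in M2 (median -1.83, percentile 0). The P-cell list had 4 falls among 5 genes (median -2.76, percentile 0) and the M-cell list 3 among 6 (median -1.54, percentile 0). The pheromone-response kinase gene spk1 fell by 4.16 ± 0.07 and the M-factor receptor gene map3 by 4.15, although only 22.7% and 15.0% of their exonic bases belong to no other gene. Of 11 nitrogen starvation genes 7 fell (median -2.33, percentile 0), with the ammonium transporter gene amt1 at -2.97. Heat shock genes had 11 rises and no fall among 14 (median 2.11, percentile 100). Proteasome genes had 5 rises and no fall among 32 (median 0.74, percentile 100), with pre5 at 1.37 ± 0.07. Ribosomal protein genes had 24 rises and 2 falls among 129 (median 0.63, percentile 100). Environmental stress genes had 3 rises and 2 falls among 16 (median -0.44, percentile 0.53, not called in the last 300 bases, with no floor or with the higher floor). The risen members were the trehalose synthase gene tps1, at 1.70 ± 0.04, zym1, at 1.58 ± 0.02, and the calcium pump gene cta3, at 1.15. The 16 wtf genes had a median of 0.60 at percentile 98.3 with 2 falls and no rise, and were not called with either smaller track, in the last 300 bases, with quantile normalization or without bases near A or T runs. Inside the central 95% were ribosome biogenesis (median -0.23), DNA replication (-0.09), mitotic M phase (0.01), histones (0.06), glycolysis (0.10), oxidative phosphorylation (-0.19) and the prp genes (0.24). Differences of the 2 gene parts had a correlation of 0.82 and a median gap of 0.29.

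M3 against M0 showed genes for the meiotic divisions and for spore formation at high levels. Of 11 meiotic divisions genes 10 rose, and of 21 spore membrane and wall genes 17 rose, with median differences of 3.99 and 3.41. The largest rise was that of meu7 (SPBC16A3.13, chromosome II, 4272341 to 4274665 on the minus strand), at 5.53 ± 0.03, from a mean coverage of 31.6 in M0 to 942 in M3. Histone genes were lower, and map2 fell by 9.81 ± 0.13. Of 4292 genes above the floor, 937 rose and 858 fell.

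Further large rises in M3 were meu17, a glucoamylase gene, at 5.48 ± 0.03, gas4, for a glucanosyltransferase of the spore wall, at 5.09 ± 0.03, the hexose transporter gene ght6, at 4.68 ± 0.04, mug95, at 4.56 ± 0.12, and hsp16, at 4.53 ± 0.08. The rises of meu6, mug137 and spo6, at 5.03, 4.69 and 4.68, are uncertain because all their exonic bases belong to another gene as well. The largest falls after map2 were put4 (-8.22 ± 0.76), isp7 (-6.84 ± 0.13), nrg1 (-6.16 ± 0.26), thi7 (-5.94 ± 0.28), isp4 (-5.76 ± 0.12), dni2 (-5.37 ± 0.16), isp5 (-5.28 ± 0.22), the phosphate transporter gene pho84 (-5.21 ± 0.12) and ste11, for the transcription factor that starts mating (-4.98 ± 0.07).

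The meiotic divisions list stood at percentile 100. The PIL domain gene meu14 rose by 4.46 ± 0.05, rem1 by 4.20 ± 0.11, the kinase gene spo4 by 4.10 ± 0.08, mei4 by 3.33 ± 0.10 and mes1 by 2.64 ± 0.05. The spore list, also at percentile 100, had 2 falls, and its rises included the septin gene spn5, at 4.28 ± 0.05, meu10, at 4.18 ± 0.02, and mde10, at 3.72 ± 0.04. Of 3 late sporulation regulators 2 rose, atf21 by 3.65 ± 0.07 and atf31 by 3.28 ± 0.06 (list median 3.28, percentile 99.8). Of 108 mug or meu genes 87 rose and 3 fell (median 2.33, percentile 100), and of 16 wtf genes 14 rose and 1 fell (median 2.67, percentile 100), with reads of similar copies not separable. The Mmi1 list had 3 rises among 5 protein-coding genes (median 3.33, percentile 99.97, and 0.87 and not called with no floor), while its noncoding member sme2 fell. Recombination had 3 rises and 4 falls among 15 genes (median 0.16, percentile 67.5), with sgo1, a protector of centromeric cohesion, at 1.92 ± 0.11, moa1 at 1.70 ± 0.31 and rec15 at -2.20 ± 0.32. Horsetail genes had 2 falls among 5 (median -0.02), including the dynein light chain gene dlc1, at -1.55 ± 0.20.

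Histones had 6 falls and no rise among 10 genes (median -1.37, percentile 0.01), with hta1 at -2.85 and pht1 at -2.12 ± 0.12. Heat shock had 10 rises and 1 fall among 14 (median 2.26, percentile 100), with bip1 at 3.89 ± 0.03. Proteasome genes had 10 rises and no fall among 32 (median 0.73, percentile 98.8), with rpn1302 at 2.01 ± 0.06. Of 22 mating genes 13 fell (median -1.37, percentile 0), of 5 P-cell genes 4 fell (median -1.80, percentile 0.575), and of 11 nitrogen starvation genes 9 fell (median -2.80, percentile 0), with amt1 at -3.81 ± 0.08. The M-cell list had 3 falls among 6 (median -0.96, percentile 3.55). DNA replication had 1 rise and 7 falls among 16 genes (median -0.73, percentile 3.77), with mik1 at 3.18 ± 0.08 against cdc22 at -2.78 ± 0.15 and the licensing gene cdc18 at -2.20 ± 0.20. Ribosome biogenesis had 2 rises and 7 falls among 27 (median -0.53, percentile 2.73). Ribosomal protein genes had 11 rises and 10 falls among 129 (median 0.15, percentile 85.7), and environmental stress 4 of each among 17 (median -0.28), where zym1 rose by 3.27 ± 0.02 and the stress gene ish1 fell by 2.64 ± 0.11. Mitotic M phase (median 0.54), glycolysis (0.08), oxidative phosphorylation (0.07) and the prp genes (-0.44) lay inside the central 95%. Differences of the 2 gene parts had a correlation of 0.83 and a median gap of 0.43, and with no centring 776 genes were higher and 1085 lower.

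**Figure D2:**
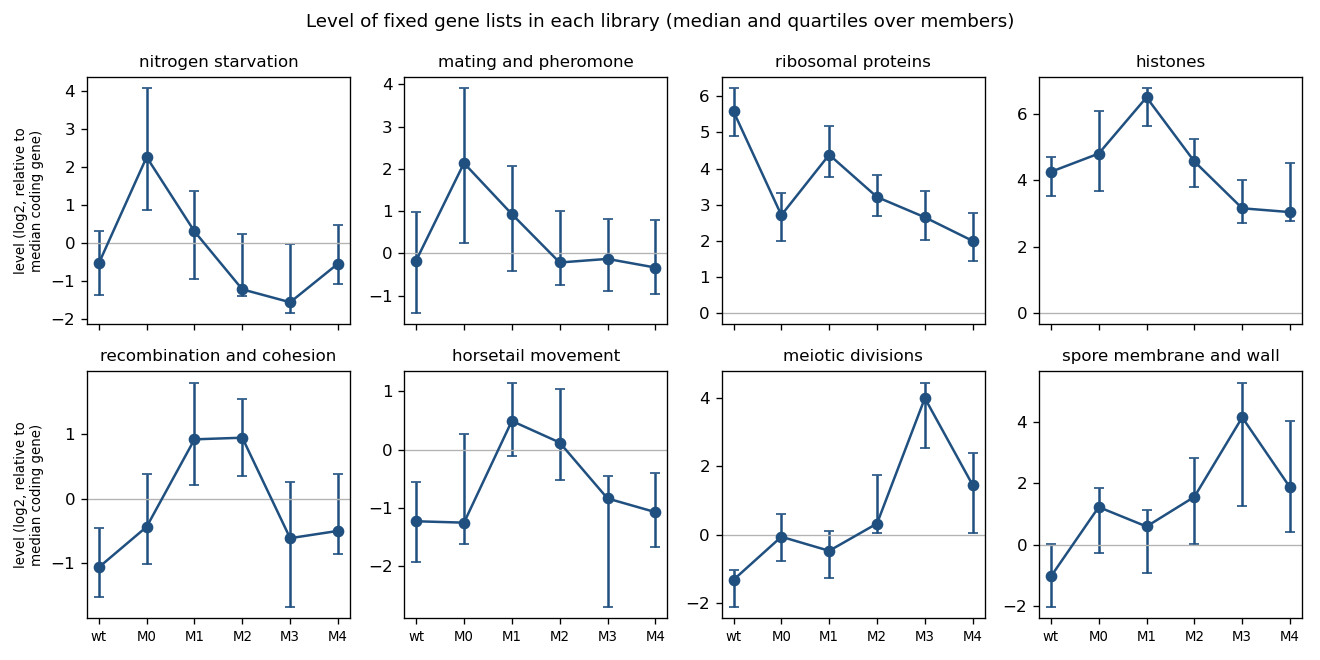
Median level (log2, relative to the median protein-coding gene of the library) of 8 of the gene lists in each library, with bars to the quartiles over members; no bar shows variation between cultures. The meiotic divisions and spore lists were highest in M3, the horsetail list in M1, and the recombination list stood at 0.92 in M1 and 0.95 in M2.

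M4 against M0 showed spore wall genes still higher and genes for histones, mating and nitrogen starvation lower. The spore-surface gene isp3 (SPAC1F8.05, chromosome I, 95790 to 96966 on the plus strand) rose by 4.88 ± 0.01, the glucanase genes eng2 and agn2 by 4.46 ± 0.03 and 4.01 ± 0.04, and mok14 by 3.51 ± 0.02. The mating pheromone gene map2 fell by 8.28 ± 0.10. Of 4256 genes above the floor, 602 rose and 477 fell. With no centring the split was 271 higher and 1785 lower.

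The largest rise was that of the heme uptake gene shu1, at 5.99 ± 0.77. So wide an error comes from few reads in M0, and its rank is uncertain. Others were mug109 at 5.17 ± 0.05, hsp16 at 4.78 ± 0.08, the proton pump gene pma2 at 4.62 ± 0.10, mug103 at 4.52 ± 0.09 and mug146 at 4.51 ± 0.08. The rise of meu6, at 5.56, rests on bases shared with another gene. The value of 4.70 for clr4, a histone methyltransferase gene, rests on shared bases too, and on the 48.7% of bases that are its own the difference was -0.26. The falls included nrg1 (-6.55 ± 0.40), isp7 (-5.56 ± 0.12), isp4 (-5.09 ± 0.14), shk2 (-4.97 ± 0.16), put4 (-4.46 ± 0.29) and mug14 (-4.17 ± 0.07).

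Of 20 spore membrane and wall genes, 13 rose and 1 fell (median 1.46, percentile 100). Of 10 meiotic divisions genes 7 rose (median 1.20, percentile 99.92), with meu14 at 1.97 ± 0.07 and rem1 at 1.35 ± 0.16. Late sporulation regulators had 2 rises among 3 (median 1.33, percentile 95.8), atf21 at 2.75 ± 0.08 and atf31 at 1.33. Of 100 mug or meu genes 54 rose and 3 fell (median 1.11, percentile 100), and of 16 wtf genes 14 rose (median 2.67, percentile 100). The Mmi1 list had 3 rises among 5 protein-coding genes (median 1.12, percentile 98.7, not called in the last 300 bases), while its noncoding member sme2 fell. Recombination (2 rises and 1 fall among 15, median 0.26) and horsetail genes (1 fall among 4, median -0.33) lay inside the central 95%.

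Of 22 mating genes 12 fell (median -1.78, percentile 0), of 5 P-cell genes 4 fell (median -3.15, percentile 0) and of 6 M-cell genes 3 fell (median -1.73, percentile 0.01; -0.65 and not called with the track ending in 1). Nitrogen starvation had 10 falls among 11 genes (median -1.88, percentile 0). Histones had 8 falls among 10 (median -1.40, percentile 0). Ribosomal protein genes had 1 rise and 21 falls among 129 (median -0.57, percentile 0), with rps2601 at -2.68 ± 0.14. Oxidative phosphorylation had 1 rise and 11 falls among 35 (median -0.63, percentile 0.545, not called in the last 300 bases), and the falls included the succinate dehydrogenase genes sdh2, by 1.60 ± 0.08, and sdh1, by 1.43. The proteasome list, with 2 rises and 2 falls among 32, had a median of -0.49 at percentile 2.04 and was not called in the last 300 bases or with the higher floor. Glycolysis had 4 rises and 5 falls among 16 (median -0.59, percentile 5.22). There tpi1 fell by 2.87 ± 0.07 and the glucose transporter gene ght5 by 2.35 ± 0.07, and the hexokinase gene hxk1 was at 2.08 ± 0.02 over the gene but at -0.47 in its last 300 bases. Heat shock had 4 rises and 1 fall among 14 (median 0.50, percentile 97.4). Ribosome biogenesis (0.23), DNA replication (-0.24), mitotic M phase (0.00), environmental stress (0.01) and the prp genes (-0.31) had medians inside the central 95%. Differences of the 2 gene parts had a correlation of 0.77 and a median gap of 0.41.

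M0 against wt set the first M library beside the library named for wild type. Genes for mating, nitrogen starvation and spore formation were higher in M0, and ribosomal protein genes were lower. The gene map2 rose by 12.94 ± 0.19, and of 129 ribosomal protein genes none rose and all but 6 fell, with a median of -2.93 at percentile 0. Of 4370 genes above the floor, 976 rose and 930 fell. If the names hold, the libraries differ in strain, ploidy, mating type, medium, temperature, RNA amplification and, for part of the proliferating RNA, depletion of uncapped RNA and random priming, so the difference belongs to none of these alone. The wt tracks alone are also named as filtered.

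Large rises after map2 were mug14 (8.40 ± 0.11), isp3 (7.83 ± 0.06), mfm1 (6.93 ± 0.16), bit2 (6.59 ± 0.27), dni2 (6.43 ± 0.12), the hexose transporter gene ght3 (6.20 ± 0.12), nrg1 (6.04 ± 0.13) and shk2 (5.69 ± 0.08). The largest falls with a unique sequence were cmt2, at -6.48 ± 0.16, and srp40, at -4.80 ± 0.11. Those of ftm2, ftm3 and ftm6, at -5.77, -5.70 and -5.40, fall in a family of similar copies, and mat3-Mc, at -7.03, is a silent copy at the mating-type locus whose value is a bound against the read floor. The ribosomal protein gene rps102 (SPAC22H12.04C, chromosome I, 898045 to 898962 on the minus strand) fell by 4.45 ± 0.04, from a mean coverage of 3958 in wt to 64.3 in M0. The reservation on near-identical copies of ribosomal protein genes applies to it.

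Of 22 mating genes 17 rose and 1 fell (median 2.32, percentile 100), with ste11 at 4.39 ± 0.03 and map3 at 3.48. All 5 P-cell genes were called, 4 of them higher (median 3.48, percentile 100), while the M-cell list had 2 rises among 6 (median 0.49, percentile 82.2). Nitrogen starvation had 8 rises among 11 genes (median 3.49, percentile 100), with isp4 at 5.51 ± 0.06 and amt1 at 4.28 ± 0.05. Spore genes had 14 rises and no fall among 18 (median 2.04, percentile 99.95), with spo13 at 4.42 ± 0.21 and mok14 at 4.20 ± 0.06, whereas meu10 was at 3.97 over the gene and at -0.48 in its last 300 bases. Meiotic divisions had 7 rises among 8 (median 1.47, percentile 98.7), with spo5 at 3.10. Of 3 late sporulation regulators 2 rose (median 1.59, percentile 96.7). Environmental stress had 8 rises and 2 falls among 15 (median 1.19, percentile 98.8, not called with no floor), with zym1 at 4.42 ± 0.05 and ctt1 at 2.96 ± 0.06. The wtf family had 14 rises among 16 (median 2.61, percentile 99.96). The mug or meu genes had 48 rises and 4 falls among 93 (median 1.11, percentile 100). Mitotic M phase genes had 5 rises and 3 falls among 16, with a median of 0.80 at percentile 98.3 that was not called under 4 other settings.

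Ribosome biogenesis had 18 falls and no rise among 30 (median -1.16, percentile 0), with the fibrillarin gene fib1 at -2.11 ± 0.05. Heat shock had 1 rise and 8 falls among 14 (median -1.47, percentile 0.43, not called in the last 300 bases). There hsp9 rose by 2.70 ± 0.02, and the mitochondrial Hsp70 gene ssc1 and the Hsp70 gene ssa2 fell by 2.67 ± 0.05 and 2.26 ± 0.03. Proteasome genes had 1 rise and 8 falls among 32 (median -0.79, percentile 0.04). The prp genes had 6 falls among 17 (median -0.76, percentile 4.02), and recombination 4 rises among 13 (0.60), horsetail 1 among 4 (-0.30), DNA replication 2 rises and 3 falls among 19 (-0.51), histones 4 and 1 among 10 (0.40), glycolysis 2 and 5 among 15 (-0.77) and oxidative phosphorylation 8 rises among 35 (0.57), all with medians inside the central 95%. Differences of the 2 gene parts had a correlation of 0.66 and a median gap of 0.73. With no centring 384 genes were higher in M0 and 2836 lower, a split that rests on the shift of 1.17 in the largest track, against 0.19 and 0.16 in the other 2.

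Over M0 to M4, 3393 protein-coding genes varied at least 2-fold, and each was assigned to the library with its highest level. The count was 665 for M0, 903 for M1, 289 for M2, 911 for M3 and 625 for M4. Of these, 613, 886, 256, 891 and 558 had the same library in all 3 tracks. With no centring the counts were 862, 1575, 571, 890 and 172, so the order of the libraries depends on the scaling. Among varying list members, all 10 nitrogen starvation genes were highest in M0, all 10 histone genes and 126 of 129 ribosomal protein genes in M1, and 9 of 11 meiotic divisions genes and 69 of 104 mug or meu genes in M3.

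Introns of the wt library had a median coverage of 9.74% of their flanking exons, over 1260 introns. The median was 14.6% in M0, 13.1% in M1, 13.01% in M2, 17.0% in M3 and 37.9% in M4. Introns at or under 3 read equivalents made up 11.2% in wt, 32.3% in M0, 29.8% in M1, 39.3% in M2, 42.0% in M3 and 40% in M4, shares that do not follow the order of the medians, and thinning M0 to the depth of M4 alone moved the median by 0.67 on the log2 scale. Against M0, 477 introns were higher relative to their exons in M4 and 64 lower, of 1197 compared. The counts were 127 higher and 205 lower of 1212 in M1, 105 and 218 of 1213 in M2, 176 and 212 of 1108 in M3, and 157 and 384 of 1126 in wt. In meu13 (SPAC222.15, chromosome I, 977709 to 978637 on the plus strand), a gene known for meiotic splicing, coverage of the first intron (977758 to 977803) was 61.8% of its exons in wt, 46.4% in M0, 6.24% in M1 and 5.81% in M2. The second intron was at 39.3%, 59.5%, 12.4% and 11.9% in the same libraries, and the third at 12.6%, 62.1%, 27.0% and 19.2%. The third intron rests on 4.6 read equivalents in wt, and its values in wt and M2 cannot be ranked. In M0 it held 0.9, so the floor of 3 sets the intron value there. In M3 and M4 the second intron was at 176% and 109% and the third at 192% and 80.5%. These rest on 11.6 read equivalents for the second in M3 and on 0.2 or fewer otherwise. The first intron's values of 41.0% in M3 and 59.7% in M4, like those of M0, rest on a few reads, and no intron of meu13 or crs1 was called because their exons lay below the floor in M0. In crs1 (SPBC2G2.09C, chromosome II) the first intron was at 60.2% in M0, 12.5% in M1 and 7.58% in M2, the second at 67.6%, 32.8% and 15.6%, and the third at 45.2%, 35.5% and 13.5%. The first intron held 2.0, 3.9 and 1.1 read equivalents and the second 0.8, 9.0 and 4.8. The floor of 3 therefore sets some of their percentages, and no fall can be read from them. The third held 4.8, 20.2 and 9.2, above that floor. Its difference from M0 was -0.35 ± 0.78 in M1 and -1.74 ± 0.86 in M2, and it was not called. Introns of rem1, mes1, mfr1 and spo4 were not compared. Among called introns, both introns of spn5 fell relative to exons in M3, the first from 91.0% to 5.85% and the second from 20.5% to 1.15%, both near an A or T run and so absent when such introns are left out. The gene itself rose by 4.28 while intron read equivalents went from 34.5 to 29.5 and from 16.2 to 10.9, so the ratios moved mainly through the exons. The first intron of spo5 fell in M2 from 19.3% to 1.51%, on 3.2 and 9.9 read equivalents, while the gene rose by 4.93. The fourth intron of gnd1 rose in M4 from 1.02% to 58.6%, on 9.7 and 32.5 read equivalents. The second intron of dga1 stood above its exons in both M0 and M4, at 485% and 14973%.

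**Figure D3:**
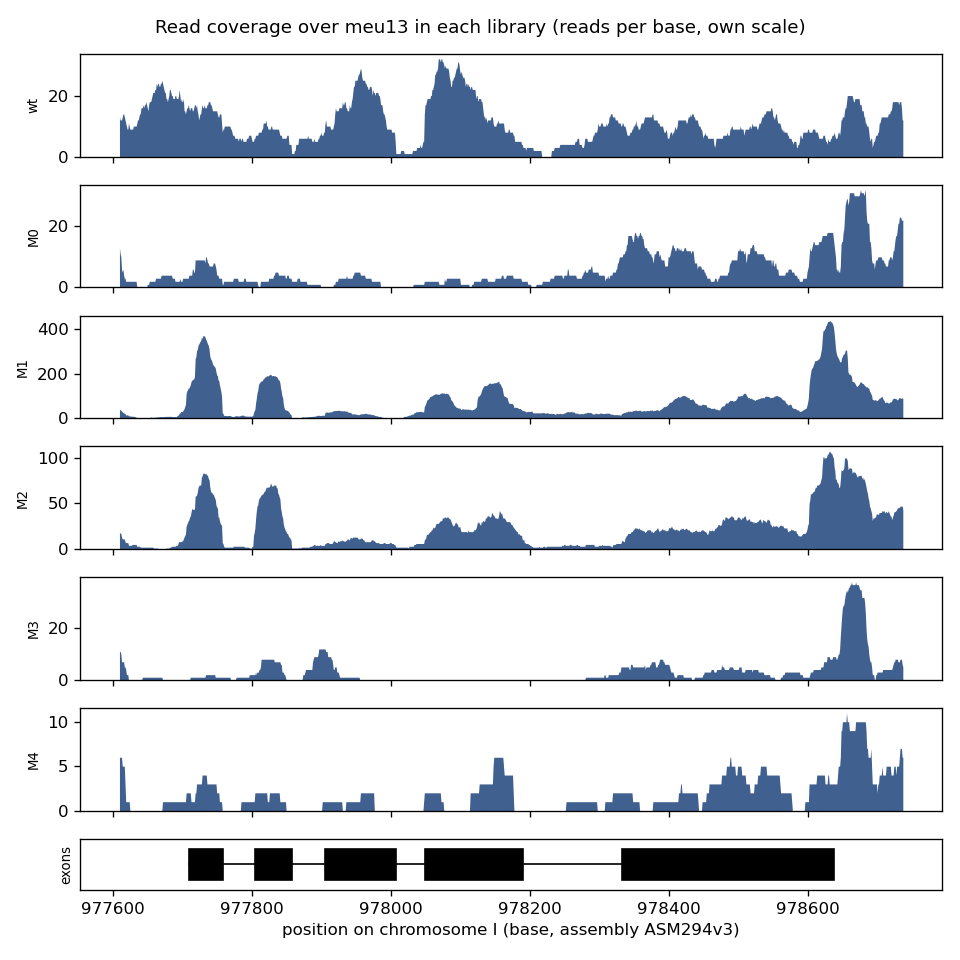
Read coverage per base over meu13 in each library, on a linear scale of its own for each panel, with exons drawn as boxes below at their positions on chromosome I. The highest coverage over the first exon was 370 in M1 and 83 in M2, and 10 in M0.

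Coverage reached 94.3% of the genome in wt, 82.4% in M0, 81.1% in M1, 82.0% in M2, 76.6% in M3 and 64.0% in M4, libraries that differ in depth. Bases outside annotated genes were covered to 77.0% in wt, 59.6% in M0 and 49.95% in M4. Of noncoding genes clear of protein-coding exons, 333 rose and 91 fell in M4 among 960 above the floor. Their median of 0.46 lay at percentile 100 of protein-coding lists, but with no centring more fell than rose (139 higher, 226 lower). In M0 against wt 384 rose and 195 fell among 896 (median 0.64, percentile 100), with a split of 255 to 501 with no centring that rests on the shift of the largest track. The counts were 135 and 106 of 831 in M1 (median -0.11, percentile 0.89; 219 and 275 with no floor, and 85 and 121 without bases near A or T runs), 85 and 145 of 778 in M2 (median -0.21, percentile 0) and 220 and 190 of 871 in M3, whose median of -0.18 at percentile 0.84 became 0.18 without bases near A or T runs. These counts mix classes of noncoding RNA. In M1 the long noncoding RNA genes went the other way from the whole count, with 51 higher and 96 lower among 617. They had 62 higher and 116 lower among 622 in M2, and 194 and 150 among 709 in M3. The counts were 276 and 83 among 777 in M4, and 358 and 88 among 648 in M0 against wt. The gene sme2, for the meiRNA that takes part in meiotic entry, rose by 2.85 ± 0.05 in M0 against wt. Against M0 it was not called in M1 and M2, at -0.88 and -0.85, and fell by 1.40 ± 0.06 in M3 and 2.27 ± 0.10 in M4. The largest noncoding rises were SPNCRNA.699 in M1 (4.71 ± 0.41), SPNCRNA.5587 in M2 (4.52), SPNCRNA.6744 in M3 (6.08 ± 0.30) and SPNCRNA.96 in M4 (5.34 ± 0.73). In M0 against wt, prl33 rose by 10.14 ± 0.33, meu3 by 8.58 ± 0.18 and meu19 by 7.97.

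**Figure D4:**
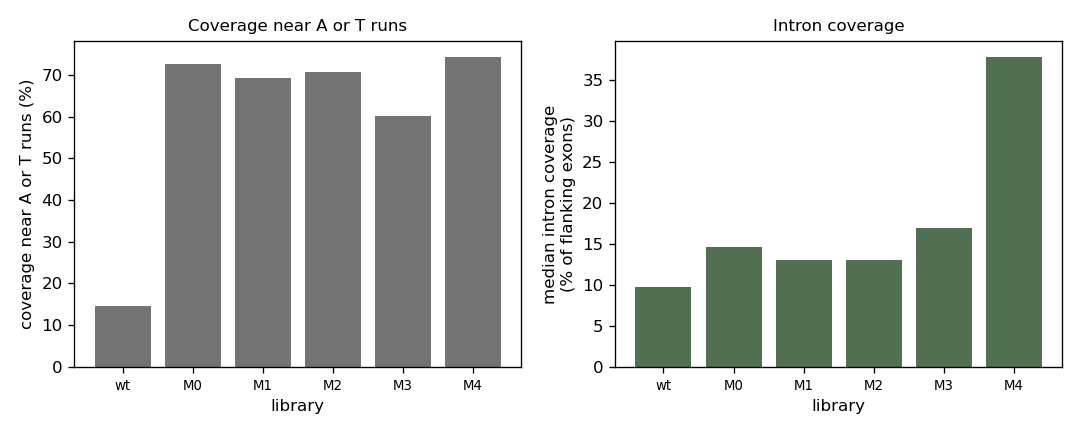
Share of coverage within reach of A or T runs (left, percent of the total) and median intron coverage (right, percent of flanking exons) in each library, 1 bar per library from 0. The left panel shows the largest track, with 74.4% in M4 and 14.5% in wt; in the track ending in 2 the share was 28.6% in M0 and 27.9% in M4. The right panel has 37.9% in M4 and 9.74% in wt, libraries that differ in depth.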

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

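The tests on reads placed at A or T runs, on even background coverage and on amplification were chosen only after the results they bear on were seen, as was that on transcription near the purest runs, and those on transcription near all runs, on depth, on short transcripts and on shared reads before. The M series moved 7 gene lists to opposite sides of the random lists in different comparisons with M0, and none of these differences between comparisons was itself tested. Among the comparisons quoted below, a call ended under some alternatives for 2 of the 7 lists. These were meiotic divisions in M1 with the track ending in 1 and with the higher floor, and the proteasome in M4 in the last 300 bases and with the higher floor. The call of the wtf family in M2, not quoted below, ended under several alternatives as well. Genes of the meiotic divisions had a median of 3.99 in M3 and -0.73 in M1, spore membrane and wall genes 3.41 in M3 and -0.72 in M1, genes named mug or meu 2.33 in M3 and -0.46 in M1, and the wtf family 2.67 in M4 and -0.84 in M1. Ribosomal protein genes went from 1.84 in M1 to -0.57 in M4, histones from 1.74 in M1 to -1.40 in M4, and proteasome genes from 0.74 in M2 to -0.49 in M4. The meiosis stages that the names stand for, if read in time order, are a biological explanation that these single libraries leave untested, and temperature and medium, which would differ between M0 and M1 to M4, stay open beside it.

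In the largest track, bases near A or T runs, which make up 3.00% of the genome, held 72.7% of the coverage in M0, 69.2% in M1, 70.7% in M2, 60.1% in M3 and 74.4% in M4, against 14.5% in wt, while the track ending in 2 had 28.6% in M0 and 3.20% in wt. Over all windows, bases 60 to 160 away, relative to the median gene, stood at 1.57 times the wt value in the median M library. The range over the 5 was 1.54 to 1.97, under the bound of 2 times set beforehand for stronger transcription of the regions around the runs. But 1911 of the 3182 windows held exactly 16 A or T and had little or no excess in the M libraries. The value over all windows therefore mostly describes windows without the pattern and cannot decide. Stronger transcription stays open for the 197 windows of 19 or 20 A or T as well, which held at least 81.0% of the window coverage. Their flanks stood at 2.07 times the wt value, with a range of 1.66 to 2.60 and an SD of 0.393 around that bound. Reads made mostly of A or T and placed on genomic runs remain a candidate explanation. Over the 3182 windows pooled, mean coverage was at least 29.4 times that of their flanks in each M library. The value was 14.0 in wt, so that wt shows the contrast as well. That excess sits in the purest windows: the 197 had ratios of 858 to 4991 in the M libraries and 659 in wt, while the 1911 with exactly 16 had 0.50 to 1.08 in the M libraries. The wt tracks alone are named as filtered, and whether a filter lowered the share in wt was not tested.

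Noncoding genes were higher relative to protein-coding genes in M4 than in M0, by a median of 0.46, and introns higher relative to their exons, by 1.25. For noncoding genes, reads at A or T runs are argued against, since the median without them was 0.72. Thinning M0 to the depth of M4, keeping 33.3% of its reads, moved the median of the same genes by -0.0017. Such thinning lowers all genes by the same share on average, and levels are centred on the median gene. It could therefore move the median of this fixed set mainly through the read floor, and it did not. The set was chosen in the full libraries, so an effect of depth on which genes pass the level floor was not tested. Lower depth therefore stays open for noncoding genes. For introns depth is a candidate explanation of part of the change, because the same thinning alone moved the median intron by 0.67. An even background of reads stays open for both: subtracting the median coverage outside genes left 0.48 and 1.4999, but that median was 0 in M4, so nothing was taken from that library, and subtraction of the mean was void because 62.4% of genes in M4 lay at or under it. The stage behind M4 is an untested biological explanation, and unspliced RNA cannot be told apart from such a background. The most common isolated covered stretch was also shorter in M4, at 29 bases against 36 in M0. Whether that difference bears on the noncoding genes or the introns was not tested.

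Ribosomal protein genes were lower in M0 than in wt with a median of -2.93 on the log2 scale. Short transcripts are argued against, because the list lay at percentile 0 among random lists matched on exonic length. Reads shared between gene copies were judged by how much coverage the largest track adds to the track ending in 2. The 48 of 129 members where it adds at most 10% in each library had a median of -2.78. Reads that only the largest track adds therefore do not account for the difference. No label says whether those are the shared reads, so shared reads stay open. Amplification of the M libraries, if the names hold, stays open, since the list stood at -1.08 in M1, -2.30 in M2, -2.81 in M3 and -3.48 in M4 against wt, a median of -2.55, and every M library would have been amplified. A first form of this test used M1 alone, the library with the smallest difference, and was replaced because 1 library excludes nothing. With the groups so divided amplification cannot be told apart from meiosis. Strain, ploidy, medium, temperature, the random priming of part of the proliferating RNA and any filter on the wt tracks remain open and untested.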

How the results depend on the processing

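The alternatives that left out bases or introns near A or T runs, or used exonic bases of 1 protein-coding gene, were chosen after seeing the data. No paired analysis was possible because the 3 tracks of a library are nested sets of the same reads and no library has a replicate. For the same reason fits that leave out a replicate were not run. Quantile normalization and the main track alone moved no count of genes by more than 1.5 times, and the count of called gene lists stayed within that factor under every alternative run. The cause of the changes below was not tested, except that a stricter size rule, a different floor and a smaller track change counts by their construction. By the median gene, depth limits M4 most, at 174 read equivalents. Genes at or under 3 read equivalents numbered 36 in M3 and 23 in M4.

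With a size rule of 1.5, protein-coding genes higher and lower were 295 and 248 in M1, 154 and 222 in M2, 597 and 471 in M3, 358 and 198 in M4, and 639 and 529 in M0 against wt. With no centring they were 271 and 1785 in M4 and 384 and 2836 in M0 against wt. Noncoding genes with no centring were 139 higher and 226 lower in M4, and 255 and 501 in M0 against wt. The genes highest in M1, M2 and M4 then numbered 1575, 571 and 172. In M0 against wt the mitotic M phase list turned to -0.37, the mug or meu list to -0.058 and the kinase gene spo4 to -0.0089, which is by construction the main value less the shift of 1.17 common to all genes in the largest track. That shift was 0.19 and 0.16 in the other tracks, too small to turn any of the 3 main values, so nothing is read from these turns.

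Noncoding counts depended on the floor. With no floor, 219 were higher and 275 lower in M1, 184 and 303 in M2, 374 and 363 in M3, 620 higher in M4, and 623 and 378 in M0 against wt. With a floor at the 50th percentile, 62 were lower in M1, 48 higher and 91 lower in M2, 135 and 108 in M3, and 209 and 55 in M4. In the last 300 exonic bases 113 were lower in M3 and 226 higher in M0 against wt, with the mean of log values 60 were lower in M4, and without bases near A or T runs 85 were higher in M1 and 125 lower in M0 against wt.

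Named genes reversed most often in their last 300 exonic bases. The checkpoint kinase gene bub1 was at 0.59 in M1, 0.22 in M2, 1.15 in M4 and -0.11 in M0 against wt, cig2 at -1.37, cdc20 at 0.28 and meu10 at -0.48 in M0 against wt, nuc1 at -0.35 in M3, and hxk1 and mpp10 at -0.47 and -0.39 in M4. With the mean of log values cdc20 was at 0.017 in M0 against wt, and nip7 and bub1 at -0.19 and 0.23 in M4. Without bases near A or T runs slp1 was at -0.38 in M0 against wt. On bases of 1 protein-coding gene prp19 was at 0.85 in M0 against wt and clr4 at -0.26 in M4.

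The median intron level relative to exons, on the log2 scale and in the order wt, M0, M1, M2, M3, M4, was -3.14, -2.48, -2.73, -2.69, -2.26 and -1.07 with the track ending in 1. It was -3.08, -2.23, -2.24, -2.36, -2.01 and -1.03 with the mean of log values, -2.62, -2.11, -2.26, -2.28, -1.68 and -0.85 with no floor, and -3.85, -3.30, -3.45, -3.52, -3.24 and -2.01 with the floor at the 50th percentile. For M0 to M4 it was -2.63, -2.79, -2.80, -2.36 and -1.20 without 10 bases at each intron end, and -2.95, -3.09, -3.15, -2.75 and -1.60 against all exons of the gene. M4 had the highest median in each of these settings. Introns higher in wt than in M0 numbered 94 with the mean of log values, 261 with no floor, 92 with the higher floor and 99 without introns near A or T runs, and those lower numbered 591 with no floor and 237 with the higher floor. With the higher floor 79 introns were higher in M1, 65 in M2, 103 in M3 and 297 in M4. With no floor 161 were higher in M2 and 317 in M3, and with the mean of log values 41 were lower in M4.

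The covered share of the genome with the tracks ending in 1 and in 2 was 85.6% and 93.3% in wt, 76.5% and 81.2% in M0, 75.9% and 80.0% in M1, 76.5% and 80.9% in M2, 71.0% and 75.6% in M3, and 55.4% and 62.8% in M4. With the threshold at the 5th percentile of exonic bases it was 88.3% in wt, and the threshold was 0 in the M libraries, where nothing moved.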

Other observations

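Small RNAs, which belong to none of the gene lists above, were also present in the coverage, with the limit of poly(A) selection. Part of the proliferating RNA was primed with random hexamers, which could by itself raise RNA without poly(A) tails in wt. Of 55 snoRNA genes clear of protein-coding exons, 2 were higher and 27 lower in M3 than in M0 among 37 above the floor, whereas in M4 18 were higher and 2 lower among 47. In M1 12 were higher and 4 lower among 44, and in M2 2 were higher and 20 lower among 38. The largest noncoding rises in M1 included snoR39a, at 3.64, and snoU24b, at 3.36. Of 170 tRNA genes, 3 were higher and 62 lower in M0 than in wt among 133 above the floor. Against M0, 45 were higher and 2 lower in M1 among 102, and 23 were higher and 3 lower in M4 among 65. Of 47 rRNA genes, 28 were lower in M0 than in wt and none higher, and 24 were higher in M1 than in M0 and none lower, with reads of repeat copies not separable.

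Coverage outside annotated genes made up 8.05% of all coverage in wt, 32.8% in M0, 30.3% in M1, 31.8% in M2, 28.8% in M3 and 37.3% in M4 in the largest track, in which 60.1% to 74.4% of the coverage of the M libraries lies near A or T runs. In the track ending in 2 it was 2.66% in wt, 12.8% in M0, 10.2% in M1, 10.7% in M2, 9.04% in M3 and 14.2% in M4. The wt tracks alone are named as filtered, which limits this comparison. Introns of protein-coding genes held 0.400% in wt and 1.86% in M4 in the largest track, and 0.343% and 0.951% in the track ending in 2. Across protein-coding genes within single libraries, which are not independent replicates, levels of M1 and M2 had a Pearson correlation of 0.92, M3 and M4 of 0.86, and wt and M3 of 0.51. Among the proteasome genes that varied at least 2-fold over the M series, 13 were highest in M2 and 16 in M3.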
